A study of Homo sapiens with 9 samples.

How the data were processed

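RNA was sequenced from MDA-MB-231 cells, an established human triple-negative breast cancer line, in 9 libraries of 3 groups with 3 libraries each. Per the labels, the groups were control cells given a control siRNA (CTL+siCTL), cells overexpressing the nuclear receptor TLX, encoded by NR2E1, given the control siRNA (TLX+siCTL), and the TLX-overexpressing cells given an siRNA against TLX (TLX+siTLX). The titles of the 3 control samples also carry the word PC3, which no label explains and which is also the name of a prostate cancer line. Their stated cell line is MDA-MB-231. Cells were transfected for 48 h and libraries were made with a stranded TruSeq mRNA kit, per the labels' protocols. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. How TLX was overexpressed and the sequences of both siRNAs are not given in the sources used here.

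The authors deposited a table of log2 CPM values, counts scaled to library size, for 27548 rows, each an Ensembl gene, and 9 libraries. Per the submitters' processing notes, kallisto 0.44.0, limma, edgeR and genome build GRCh38 were used, with no role or order given. A further table deposited by the authors holds, for each of the 3 comparisons between groups, a signed fold change, a raw p-value and a false discovery rate per gene. A fall is written there as minus the inverse ratio. Which test gave the authors' deposited p-values is not given in the sources used here. Each column of the log2 CPM table names its group and a running number that is in no sample's labels, so the libraries are called S1 to S9 as numbered in the table, and 0 columns were left unmapped.

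The lowest log2 value was -5.33 in all 9 libraries, which fits a count of 0 with a prior count of 2. From the steps between low values, each library's effective size was recovered as 73.8 to 91.8 M reads. Only 29.7% to 30.7% of the values lay within 0.01 of a whole read, and 18.4% to 20.0% of the rows of a library were at 0. The reads rebuilt in this way are therefore estimated, not whole, and were used only for counting intervals and for an added alternative. Such intervals cover counting error only. Pairs of libraries in a group were compared with a chi-square statistic per gene on genes with at least 50 rebuilt reads. It ranged from 9.22 to 55.3, where counting noise alone gives about 1, so no pair was a repeat of 1 library. The largest values were those of S9 with S7 (55.3) and with S8 (32.2).

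Of the 27548 rows, 2303 repeated the symbol of another row, and 2296 of these were outside the annotation of the primary assembly. Reads of such genes, and of near-identical paralogs and pseudogenes, can be split between rows, and their values are uncertain. Genes were placed on GRCh38 by Ensembl identifier with the GENCODE 29 annotation, in which 24790 of the identifiers were found.

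Each comparison was tested with limma 3.58.1 in R 4.3.3 on the log2 CPM values as deposited, in 1 fit of all 9 libraries with a mean per group, moderated with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the 27548 rows and a threshold of 0.05. Log2 fold changes are given with the moderated standard error (SE), and group values as mean ± SD (n = 3). The deposited log2 values hold a prior count, read here from that lowest value, so fold changes of genes with few reads are understated. For NR2E1 a ratio of rebuilt reads with an exact 95% binomial interval was added. The moderated F test over the 3 groups was run in the same fit. Simulated data for TLX+siCTL against CTL+siCTL had the real means and spreads and 200 of 27548 rows changed. All 200 had a mean log2 CPM of at least 1. Of the planted 1.2-fold changes 20.0% were recovered, as were 78.0% of the 1.5-fold, 96.0% of the 2-fold and 100.0% of the 4-fold changes. Of the calls 3.92% were false. Far fewer rows changed there than were called in the real comparison, so the rates hold for that setting only.

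The 31 gene lists held 806 genes and were fixed before the data were examined. For them 1 row per symbol with a mean log2 CPM of at least -3 counted as measured, which left 15767 rows as the background. This background was not part of the design fixed beforehand. It was chosen after a look at the lists with all 27548 rows as the background, which is given as an added alternative. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 31 lists of a comparison, and with fry, which tests whether a list's genes move on balance one way. Camera was repeated with a correlation estimated per list. With limma's camera at an estimated correlation 0 of the 31 lists stayed under an adjusted p of 0.05 in each of the 3 comparisons, against 14 called in each with the preset correlation. The smallest adjusted p values were 0.115, 0.0505 and 0.0646, and 7, 10 and 5 lists had an unadjusted p under 0.05. With all rows as the background and an estimated correlation, 9 of the 42 list calls stayed under 0.05, so whether any list call holds with an estimated correlation depends on the background.

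Genes were named by a rule fixed before the data were examined. It took NR2E1, the 10 largest rises and the 10 largest falls of each comparison, up to 4 genes of each described list by adjusted p, and the 5 genes in each direction with the largest opposite changes in the 2 steps. The largest changes had to have an adjusted p under 0.05, a symbol that is not a placeholder, a mean log2 CPM of at least 1 and no overlap between the groups compared. A further condition was added after the data were seen, that of several rows with 1 symbol only the row in the primary annotation, or else the one with the highest mean, could be named. Without it the rule would also have taken TCF19 and HLA-DRA, each on repeated rows outside the primary annotation, and the report gives their values. Some genes that the rule took are not reported here. Chance gives no overlap in 10% of genes for groups of 3.

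Overlaps between comparisons that share libraries were set beside 100 simulations of 9 unchanged libraries with the fitted spread, and beside the overlap of independent lists. The shared groups have 3 libraries each and could not be split into parts of at least 2. Settings tried were no intensity trend, a robust spread, the 6 libraries of a comparison alone, each library left out, a minimum mean log2 CPM of 1, centring on library medians, quantile normalization for the counts and single genes, log2(CPM + 1), and a minimum log2 fold change of 1. Added after the data were seen were limma voom on the rebuilt reads, the ratio of NR2E1 reads with each library left out, 1 row per symbol, centring on genes with a mean log2 CPM of at least 1, quantile normalization and other backgrounds for the lists, sums over the rows of a symbol, and leaving out genes that hold a certain 7-mer in the 3' UTR. That 7-mer came from a scan of 15632 7-mers, each in at least 100 genes, over the annotated 3' UTRs (at least 50 bases) of 11175 genes with a mean log2 CPM of at least 1, after regressing out UTR length, GC content and expression, with 100 shuffles of the residuals over genes. Tested on simulated data, the scan put a planted 7-mer with an effect of -0.15 first in 20 of 20 runs.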

Results

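Gene expression was measured by RNA sequencing in MDA-MB-231 cells, a triple-negative breast cancer line, in 3 groups of 3 libraries. Control cells with a control siRNA (CTL+siCTL) were libraries S1 to S3, TLX-overexpressing cells with the control siRNA (TLX+siCTL) S4 to S6, and TLX-overexpressing cells with an siRNA against TLX (TLX+siTLX) S7 to S9. The cell line stated for all samples is MDA-MB-231, while the titles of the control samples also carry PC3, a prostate line's name that no label explains, and whether the control cells differ from the others besides TLX is not given in the sources used here. Effective library sizes were 80.7, 76.2 and 73.8 M reads in CTL+siCTL, 91.8, 78.7 and 79.4 M reads in TLX+siCTL, and 81.3, 76.7 and 87.0 M reads in TLX+siTLX. The 10 most abundant genes took 5.21% to 6.04% of a library. S9 stood furthest from the other libraries of its group, with a chi-square per gene of 55.3 against S7 and 32.2 against S8, where S7 and S8 gave 23.9. Of the 27548 rows, 12564 had a mean log2 CPM of at least 1.

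NR2E1, which encodes the orphan nuclear receptor TLX (ENSG00000112333, GRCh38 chromosome 6, 108166058 to 108188809), was near the floor in control cells, highest in TLX+siCTL and between these in TLX+siTLX. Its log2 CPM was -4.59, -4.28 and -4.50 in CTL+siCTL, 0.28, -0.84 and 0.23 in TLX+siCTL, and -2.61, -3.40 and -1.77 in TLX+siTLX. Group means were -4.46 ± 0.16, -0.11 ± 0.63 and -2.59 ± 0.82 (SD, n = 3). The mean of NR2E1 in TLX+siCTL was above that of 50.98% of all rows. In rebuilt reads NR2E1 was 44.9-fold higher in TLX+siCTL than in CTL+siCTL (exact 95% interval 19.0 to 139.5). In TLX+siTLX it was at 0.168 of the TLX+siCTL level (0.117 to 0.235) and 7.54-fold above CTL+siCTL (2.97 to 24.5). S9 held 23.4 of the 40.1 TLX+siTLX reads, and without it these ratios were 0.111 (0.0634 to 0.181) and 4.97 (1.76 to 17.2). The limma log2 fold changes were 4.35 ± 0.47 (SE, adjusted p = 0.000133), -2.48 ± 0.47 (adjusted p = 0.00494) and 1.86 ± 0.47 (adjusted p = 0.0134) in the same order. The difference from control cells that was left after the siRNA lost its call without S1 (1.80, adjusted p = 0.0549) and on the log2(CPM + 1) scale (0.18, adjusted p = 0.387), with adjusted p from 0.00668 to 0.387 over the settings tried. The authors' deposited table gives signed fold changes of 33.95, -6.21 and 5.47 for NR2E1.

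**Figure D1:**
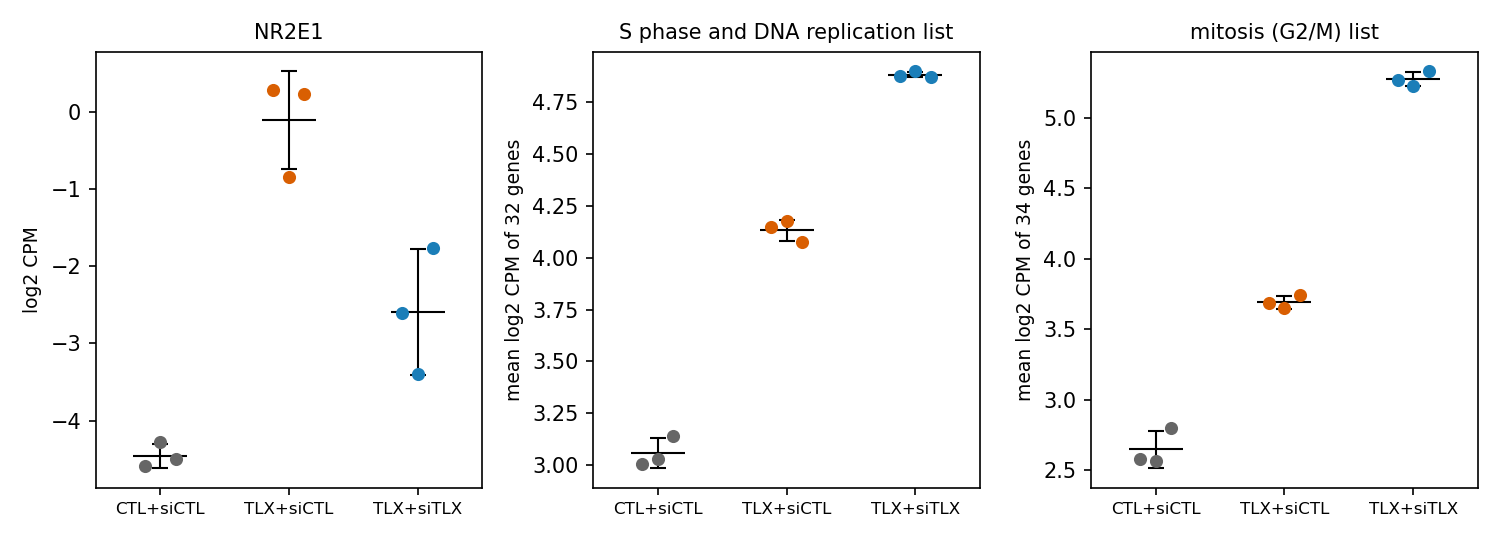
NR2E1 in log2 CPM (left) and the mean log2 CPM of the S phase list (32 genes, middle) and of the mitosis list (34 genes, right) in the 3 groups. Points are libraries, bars the mean and error bars the SD (n = 3); NR2E1 was highest in TLX+siCTL, while both list means were highest in TLX+siTLX.

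The comparison of TLX+siCTL with CTL+siCTL shows what differed between TLX-overexpressing and control cells. Other differences between these cells cannot be told apart from TLX. Cell cycle genes were higher, and inflammatory, interferon-stimulated and sterol synthesis genes were lower. Of 32 measured genes of S phase and DNA replication, 30 rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 fold change of 1.06. They included UHRF1, a maintenance factor of DNA methylation (1.81 ± 0.05, SE), the transcription factor E2F1 (1.64 ± 0.05), the helicase subunit MCM3 (1.30 ± 0.04) and the thymidylate synthase TYMS (1.62 ± 0.06). Camera gave an adjusted p of 5.41e-14 for the list, and adjusted p = 0.115 with an estimated correlation. Of 34 mitosis genes, 31 rose and 1 fell (31 and 1 adjusted over the list alone; median 1.11, adjusted p = 5.61e-13), among them the checkpoint kinase BUB1 (1.33 ± 0.05), the cyclin CCNA2 (1.41 ± 0.08) and ANLN (1.73 ± 0.09). For mitosis the adjusted p = 0.189 with an estimated correlation.

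NF-kB and inflammatory, interferon-stimulated and immediate early genes fell in TLX+siCTL. Of 29 NF-kB and inflammatory genes, 25 fell and 1 rose (26 and 1 adjusted over the list alone; median -1.14, adjusted p = 6.86e-10, adjusted p = 0.134 with an estimated correlation). The chemokines CXCL3 (-2.60 ± 0.08) and CXCL2 (-2.12 ± 0.07), the cytokine IL6 (-2.55 ± 0.09) and the complement component C3 (-2.43 ± 0.10) were among them. Of 40 interferon-stimulated genes, 30 fell and 3 rose (32 and 3 adjusted over the list alone; median -0.92, adjusted p = 1.82e-09, adjusted p = 0.134 with an estimated correlation), with ISG15 at -1.16 ± 0.03 and OASL at -1.78 ± 0.05. Immediate early and MAPK feedback genes fell in 19 of 29 cases and rose in 4 (19 and 5 adjusted over the list alone), with EGR1 at -2.35 ± 0.14 and FOS at -1.56 ± 0.10. Their median was -0.46 (adjusted p = 0.000762, adjusted p = 0.36 with an estimated correlation).

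Cholesterol, fatty acid and unfolded protein response genes also fell. Of 25 cholesterol synthesis genes, 18 fell and 1 rose (19 and 1 adjusted over the list alone; median -0.69, adjusted p = 5.3e-06, adjusted p = 0.433 with an estimated correlation), including MVD, an enzyme of the mevalonate pathway (-1.31 ± 0.09). Of 16 cholesterol efflux and oxysterol genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.49, adjusted p = 0.00211, adjusted p = 0.189 with an estimated correlation), with CH25H at -1.71 ± 0.17. Of 29 fatty acid metabolism genes, 18 fell and 2 rose (21 and 2 adjusted over the list alone; median -0.33, adjusted p = 3.15e-05, adjusted p = 0.189 with an estimated correlation); ACSL3 fell by 1.56 ± 0.07 and DGAT2, a triglyceride synthesis enzyme, rose by 2.10 ± 0.10. Of 32 unfolded protein response and ATF4 target genes, 25 fell and 4 rose (27 and 4 adjusted over the list alone; median -0.50, adjusted p = 1.24e-06, adjusted p = 0.36 with an estimated correlation), with XBP1 at -0.65 ± 0.03 and DDIT3 at -1.34 ± 0.07.

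Epithelial markers fell in 10 of 19 cases and rose in 1 (12 and 2 adjusted over the list alone; median -0.49, adjusted p = 0.000762, adjusted p = 0.189 with an estimated correlation). The transcription factor ELF3 fell by 2.38 ± 0.06 and the adherens junction gene CDH1 by 3.03 ± 0.27. Luminal breast markers, fixed as markers of another cell line, fell in 9 of 14 cases and rose in 3 (9 and 3 adjusted over the list alone; median -0.57, adjusted p = 0.0254, adjusted p = 0.433 with an estimated correlation), with SPDEF at -2.27 ± 0.13. That call was lost among genes with a mean log2 CPM of at least 1 (adjusted p = 0.080). Prostate markers, also of another cell line, fell in 2 of 6 cases and rose in 0 (2 and 0 adjusted over the list alone, camera adjusted p = 0.612, fry adjusted p = 0.00711, down). These were TRPM8 (-1.65 ± 0.35) and SLC45A3 (-0.28 ± 0.07), which lost its call with library medians centred (adjusted p = 0.111). Small rises were found in ribosomal protein genes, of which 33 of 47 rose and 1 fell (35 and 1 adjusted over the list alone; median 0.23, adjusted p = 2.52e-07, adjusted p = 0.433 with an estimated correlation). Oxidative phosphorylation genes rose in 19 of 37 cases and fell in 4 (21 and 5 adjusted over the list alone; median 0.13, adjusted p = 0.0177, adjusted p = 0.465 with an estimated correlation). Antigen presentation genes rose in 8 of 20 cases and fell in 2 (9 and 2 adjusted over the list alone; median 0.48, adjusted p = 0.0177, adjusted p = 0.216 with an estimated correlation), and most HLA and TAP genes are on several rows and are uncertain.

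Other lists had genes that rose and genes that fell, without a camera call. Fry, which does not set a list against other genes, gave adjusted p = 0.00262 for mesenchymal genes, 1.07e-05 for integrin and adhesion genes and 0.000133 for growth factors and receptors, all down. Mesenchymal genes fell in 12 of 23 cases and rose in 6 (12 and 6 adjusted over the list alone; median -0.38, adjusted p = 0.126), with FN1 at -2.02 ± 0.06, the transcription factor SNAI2 at 1.34 ± 0.04 and the receptor kinase AXL at 1.13 ± 0.04. Integrin and adhesion genes fell in 14 of 28 cases and rose in 9 (14 and 9 adjusted over the list alone; median -0.26, adjusted p = 0.132), with ITGA2 at -1.54 ± 0.06. Growth factors and receptors fell in 12 of 30 cases and rose in 9 (12 and 10 adjusted over the list alone; median 0.08, mean -0.31, adjusted p = 0.371), with the EGFR ligand AREG at -2.53 ± 0.09.

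Among the genes taken by the naming rule for large rises, the endotoxin receptor TLR4 (ENSG00000136869, chromosome 9, 117704175 to 117724730) rose by 3.92 ± 0.06 (adjusted p = 1.06e-08). SERPINB2 rose by 5.29 ± 0.17 but lay just under the rule's minimum mean log2 CPM, at 0.99. FAT3, ILDR2, ZNF367, the neurotrophin receptor NGFR, MCM10, PSG6, CCDC190 and GINS2 rose by 2.24 to 2.87. CD24, a surface glycoprotein (chromosome 6, 106969831 to 106975627), fell by 3.40 ± 0.20 (adjusted p = 4.77e-06). TRIML2, SLC14A1, ATP10A, LCN2, VNN3, RASSF9, B4GALNT3, SLCO4C1 and PI3 fell by 2.77 to 3.33. CD24 and PSG6 have near-identical copies or relatives, so their values are uncertain. A TCF19 row outside the primary annotation, which the rule takes without the later condition, rose by 2.98 ± 0.76 (adjusted p = 0.0165) and its symbol is on 7 rows.

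In all, 8304 of 27548 rows changed by limma (30.1%), 4142 up and 4162 down, and 652 rose and 1079 fell at least 2-fold. Of the 12564 rows with a mean log2 CPM of at least 1, 56.6% changed, 3678 up and 3438 down. The share of changed genes in a list is better set beside that. With library medians of all rows centred the share of rises among the calls went from 49.9% to 64.9%, as centring moved all fold changes by 0.12. Quantile normalization gave 53.7%. Centring on genes with a mean log2 CPM of at least 1 gave 4371 rises and 3992 falls. The balance of rises and falls thus depends on the scaling, most on centring over all rows. The authors' deposited table has 8284 genes with a false discovery rate under 0.05, and 8041 were called in both.

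The comparison of TLX+siTLX with TLX+siCTL asks what the siRNA against TLX changed in the overexpressing cells. Cell cycle genes were higher again, although NR2E1 was lower. Of 34 mitosis genes, 33 rose and 0 fell (34 and 0 adjusted over the list alone; median 1.62, adjusted p = 1.03e-23, adjusted p = 0.0613 with an estimated correlation). ANLN, a cytokinesis scaffold (2.36 ± 0.09), the topoisomerase TOP2A (2.27 ± 0.09), TPX2 (1.41 ± 0.05) and KIF23 (1.59 ± 0.06) were among them. Of 32 S phase genes, 29 rose and 0 fell (30 and 0 adjusted over the list alone; median 0.67, adjusted p = 9.44e-13, adjusted p = 0.0505 with an estimated correlation), with UHRF1 at 1.07 ± 0.05 and TYMS at 1.01 ± 0.06.

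Mesenchymal, integrin and TGF-beta target genes rose in TLX+siTLX. Of 23 mesenchymal genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone; median 0.79, adjusted p = 3.19e-09, adjusted p = 0.0505 with an estimated correlation), with the collagen COL5A1 at 1.88 ± 0.06, the fibronectin FN1 at 1.12 ± 0.06 and LOXL2 at 1.07 ± 0.04. Of 28 integrin and adhesion genes, 18 rose and 2 fell (18 and 2 adjusted over the list alone; median 0.49, adjusted p = 3.49e-07, adjusted p = 0.0505 with an estimated correlation), with ITGB3 at 1.29 ± 0.05 and ITGB8 at 1.85 ± 0.13. Of 25 TGF-beta target genes, 16 rose and 3 fell (17 and 3 adjusted over the list alone; median 0.46, adjusted p = 8.44e-05, adjusted p = 0.11 with an estimated correlation), with TGFBI at 1.67 ± 0.06. With each library left out 14 to 16 of the TGF-beta target genes rose and 0 to 2 fell, 0 without S6 or S9. Epithelial markers rose in 11 of 19 cases and fell in 0 (12 and 1 adjusted over the list alone; median 0.38, adjusted p = 0.00225, adjusted p = 0.156 with an estimated correlation), and CDH1 rose by 2.41 ± 0.27. Without S6 the epithelial median was 0.24 (adjusted p = 0.00255). Growth factors and receptors rose in 17 of 30 cases and fell in 1 (17 and 1 adjusted over the list alone; median 0.30, adjusted p = 0.000166, adjusted p = 0.115 with an estimated correlation), with EPHB2 at 0.85 ± 0.04.

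Hypoxia and glycolysis genes rose in 29 of 36 cases and fell in 2 (30 and 2 adjusted over the list alone; median 0.46, adjusted p = 6.89e-10, adjusted p = 0.09 with an estimated correlation), including the prolyl hydroxylase P4HA1 (0.90 ± 0.05). Interferon-stimulated genes rose in 20 of 40 cases and fell in 2 (22 and 2 adjusted over the list alone; median 0.32, adjusted p = 3.12e-05, adjusted p = 0.149 with an estimated correlation), with ISG15 at 0.77 ± 0.03 and OAS1 at 1.71 ± 0.12. Antigen presentation genes rose in 8 of 20 cases and fell in 0 (8 and 0 adjusted over the list alone; median 0.42, adjusted p = 0.00324, adjusted p = 0.115 with an estimated correlation), with CD74, the invariant chain, at 1.35 ± 0.06. Rows of HLA-DRA outside the primary annotation rose by 2.32 ± 0.10 (adjusted p = 3.34e-06), on 5 rows of the symbol. Unfolded protein response and ATF4 target genes fell in 22 of 32 cases and rose in 1 (24 and 1 adjusted over the list alone; median -0.33, adjusted p = 2.72e-09, adjusted p = 0.156 with an estimated correlation), with DDIT3 at -1.26 ± 0.07 and TRIB3 at -1.03 ± 0.06. NRF2 and oxidative stress genes fell in 16 of 26 cases and rose in 5 (17 and 5 adjusted over the list alone; median -0.31, adjusted p = 0.000541, adjusted p = 0.122 with an estimated correlation), with GCLM at -0.84 ± 0.07. Cholesterol synthesis genes fell in 8 of 25 cases and rose in 1 (10 and 1 adjusted over the list alone; median -0.32, adjusted p = 0.00195, adjusted p = 0.606 with an estimated correlation), with STARD4 at -1.03 ± 0.12. Without S9 the cholesterol synthesis median was -0.13 (adjusted p = 0.0116), and with each library left out 2 to 8 of its genes fell. Immediate early genes fell in 12 of 29 cases and rose in 7 (16 and 8 adjusted over the list alone; median -0.19, adjusted p = 0.0424, adjusted p = 0.59 with an estimated correlation). That call was lost under 4 other settings (adjusted p = 0.051 to 0.067), without S5 (0.0719) and without S7 (0.0643).

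By the naming rule the largest rises after the siRNA were in SPNS2, a sphingosine-1-phosphate transporter (2.71 ± 0.14), CCN5 (2.62 ± 0.16), MALL (2.55 ± 0.13) and the mitotic kinase PLK1 (chromosome 16, 23677656 to 23690367; 2.46 ± 0.16, adjusted p = 1.61e-05). KIF20A, PEG10, GDF5 and HJURP rose by 2.22 to 2.34. The xenobiotic-metabolising enzyme CYP1A1 (chromosome 15, 74719542 to 74725610) fell by 2.85 ± 0.12 (adjusted p = 3.34e-06), KLHDC7B by 2.72 ± 0.12 and CDKN2AIPNL by 2.21 ± 0.11. The cyclooxygenase PTGS2 fell by 2.05 ± 0.18, the collagenase MMP1 by 1.86 ± 0.08, and VNN3, TMEM87A, PARM1 and MTMR12 by 1.40 to 1.99. PTGS2 is in the NF-kB and inflammatory list, of which 13 of 29 genes rose here and 6 fell. Adjusted over the list alone these were 16 and 8, with a median of 0.20 and a camera adjusted p = 0.224. TMEM50B, which is on 2 rows, fell by 2.04 ± 0.49 (adjusted p = 0.0164) and lost its call without S4, S5, S7, S8 or S9 (adjusted p = 0.0593, 0.0619, 0.0522, 0.0802 and 0.0645). The 3' UTRs of CYP1A1 and MTMR12 hold the 7-mer ACACTCT, picked in this comparison as the one with the lowest z, and of 941 genes that hold it 39.1% fell, against 21.1% of 10234 others.

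In this comparison 6518 rows changed by limma (23.7%), 3507 up and 3011 down, and 733 rose and 213 fell at least 2-fold. Of the 12564 rows with a mean log2 CPM of at least 1, 45.8% changed, 2990 up and 2766 down. Without S9, 6163 rows changed. With library medians of all rows centred the share of rises among the calls went from 53.8% to 29.9%, as centring moved all fold changes by -0.14. Quantile normalization gave 45.8%. Centring on genes with a mean log2 CPM of at least 1 gave 3235 rises and 3508 falls. The authors' deposited table has 6920 genes under a false discovery rate of 0.05, and 6400 were called in both.

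**Figure D2:**
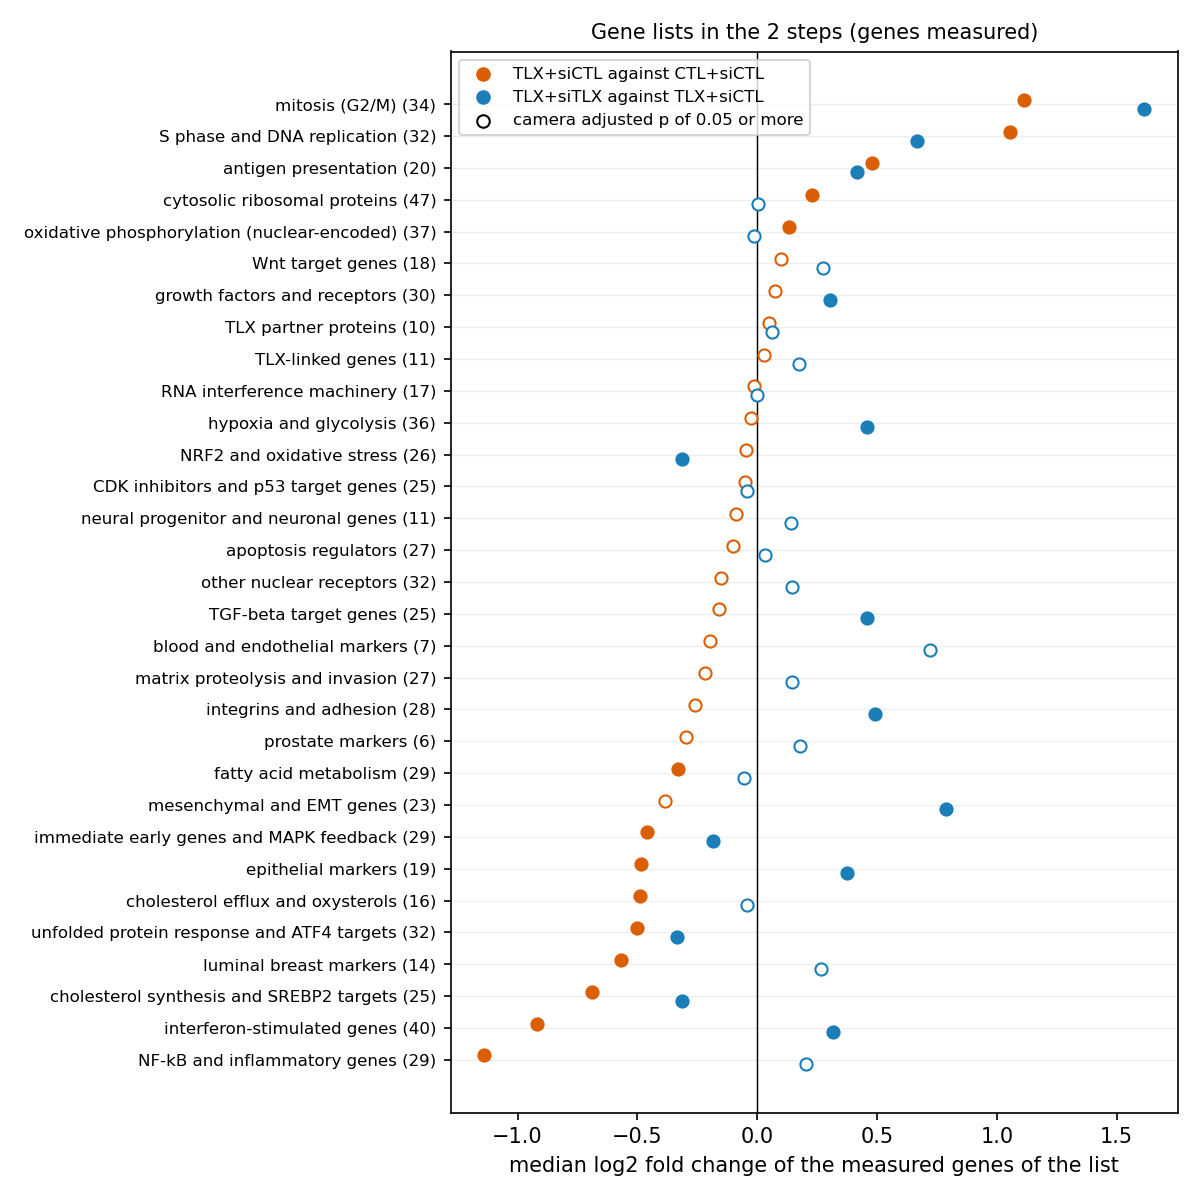
Median log2 fold change of the measured genes of each of the 31 lists, with the number measured in brackets, for TLX+siCTL against CTL+siCTL and TLX+siTLX against TLX+siCTL. Filled points have a camera adjusted p under 0.05 at the preset correlation; the mitosis list had medians of 1.11 and 1.62.

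The comparison of TLX+siTLX with CTL+siCTL shows what differed from control cells with TLX overexpressed and then targeted. All 34 mitosis genes rose (34 adjusted over the list alone; median 2.59, adjusted p = 3.76e-21, adjusted p = 0.106 with an estimated correlation), and all 32 S phase genes rose (32 adjusted over the list alone; median 1.69, adjusted p = 6.29e-18, adjusted p = 0.0646 with an estimated correlation). Mean log2 CPM of the mitosis list was 2.65 ± 0.13, 3.69 ± 0.05 and 5.27 ± 0.05 (SD, n = 3) in CTL+siCTL, TLX+siCTL and TLX+siTLX. Of 20 antigen presentation genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone; median 0.97, adjusted p = 3.11e-05, adjusted p = 0.106 with an estimated correlation). Hypoxia and glycolysis genes rose in 23 of 36 cases and fell in 5 (23 and 5 adjusted over the list alone; median 0.41, adjusted p = 0.000255, adjusted p = 0.282 with an estimated correlation). Ribosomal protein genes rose in 29 of 47 cases and fell in 1 (32 and 1 adjusted over the list alone; median 0.20, adjusted p = 7.78e-06, adjusted p = 0.582 with an estimated correlation). Mesenchymal genes rose in 12 of 23 cases and fell in 5 (12 and 5 adjusted over the list alone; median 0.62, adjusted p = 0.036, adjusted p = 0.343 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.0585) and among genes with a mean log2 CPM of at least 1 (adjusted p = 0.0775).

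Lower than in control cells were cholesterol synthesis genes, 21 of 25 fallen and 0 risen (21 and 0 adjusted over the list alone; median -0.90, adjusted p = 1.33e-07, adjusted p = 0.413 with an estimated correlation). Unfolded protein response and ATF4 target genes fell in 26 of 32 cases and rose in 4 (26 and 4 adjusted over the list alone; median -0.79, adjusted p = 3.77e-09, adjusted p = 0.269 with an estimated correlation). NF-kB and inflammatory genes fell in 19 of 29 cases and rose in 3 (19 and 4 adjusted over the list alone; median -0.51, adjusted p = 2.54e-05, adjusted p = 0.269 with an estimated correlation). Interferon-stimulated genes fell in 24 of 40 cases and rose in 7 (27 and 9 adjusted over the list alone; median -0.39, adjusted p = 0.00142, adjusted p = 0.293 with an estimated correlation). Immediate early genes fell in 18 of 29 cases and rose in 4 (18 and 4 adjusted over the list alone; median -0.42, adjusted p = 0.000199, adjusted p = 0.282 with an estimated correlation). Fatty acid metabolism genes fell in 18 of 29 cases and rose in 3 (18 and 3 adjusted over the list alone; median -0.41, adjusted p = 0.000123, adjusted p = 0.269 with an estimated correlation). Cholesterol efflux genes fell in 10 of 16 cases and rose in 1 (11 and 1 adjusted over the list alone; median -0.38, adjusted p = 0.00639, adjusted p = 0.269 with an estimated correlation). NRF2 genes fell in 15 of 26 cases and rose in 3 (16 and 5 adjusted over the list alone; median -0.35, adjusted p = 0.0106, adjusted p = 0.282 with an estimated correlation).

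Among the genes taken for large rises against control cells were CCDC190 (4.44 ± 0.10), GDF5 (4.32 ± 0.10), NGFR (4.24 ± 0.15) and ANLN (4.09 ± 0.09), while MCM10, ZNF367, KIF18B, TLR4 and DLGAP5 rose by 3.46 to 3.58. TCF19, on the row outside the primary annotation, rose by 3.93 ± 0.76 (adjusted p = 0.00329). KLHDC7B fell by 5.43 ± 0.12, VNN3 by 4.98 ± 0.20 and PTGS2 by 4.81 ± 0.18, from 9.90 to 5.09 log2 CPM. SLC14A1, RND1, SLCO4C1, SIPA1L2, TRIML2, the growth factor EREG and TMEM45B fell by 3.24 to 4.44. By limma 9544 rows changed (34.6%), 4869 up and 4675 down, and 1277 rose and 1088 fell at least 2-fold. Of the 12564 rows with a mean log2 CPM of at least 1, 63.6% changed, 4071 up and 3921 down. The authors' deposited table has 9429 genes under a false discovery rate of 0.05, and 9241 were called in both.

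Whether the siRNA undid the changes that came with TLX was read from the overlap of the comparisons. INHBB, an inhibin subunit, fell by 2.11 ± 0.18 with TLX and rose by 1.98 ± 0.18 after the siRNA, and the same held for LFNG (-1.95 and 2.06), HPGD (-1.99 and 1.92), PCDH7 (-1.87 and 2.18) and SYNPO (-2.08 and 1.83). DOCK9 (1.54 and -1.14), TPTEP1 (1.19 and -1.14), the calcium-binding CALB1 (1.45 and -1.08), GABRP (1.46 and -0.98) and MT1F (1.25 and -0.93) went the other way. MT1F, one of a family of near-identical genes, lost its call in the siRNA step without S5 (adjusted p = 0.051). In total 2297 rows changed in opposite directions, 1044 up then down and 1253 down then up. Unchanged simulated groups gave 0, but with no gene changed hardly any call could arise there, so this 0 is no measure of reversal. Independent lists would give 982.6. A further 1671 rows changed the same way in both steps, 967 up and 704 down, against 982.2 for independent lists. The numbers for independent lists take all 27548 rows as equally likely to be called. Among the 12564 rows with a mean log2 CPM of at least 1, 56.6% and 45.8% changed in the 2 steps, against 30.1% and 23.7% of all rows. Independent lists would thus overlap more than these numbers. The excess of 2297 over them is overstated, and for 1671 these numbers do not show any excess. Of the 34 mitosis genes 30 rose in both steps, as did 27 of the 32 S phase genes, while 17 of the 40 interferon-stimulated genes fell and then rose. Of the rows changed with TLX, 27.7% changed in the opposite direction after the siRNA, 20.1% in the same direction, and 52.2% had no call there. For 1215 rows (14.6%) the siRNA step was opposite and no call against control cells was left.

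Both TLX groups differed from control cells in the same direction in 5872 rows, 3023 up and 2849 down, and 340 rows differed in opposite directions. Independent lists over all 27548 rows would give 1438.4 in the same direction, a number too low for the reason given above. Across the 12564 rows with a mean log2 CPM of at least 1, which are not independent replicates, the log2 fold changes of the steps had a Pearson correlation of -0.068 and a Spearman correlation of -0.093. In simulated groups without changed genes, the shared TLX+siCTL libraries alone gave -0.500. Real changes add to the spread, so the simulated correlations cannot be set directly against the observed ones, while covariances can. Their covariance was -0.0160 against -0.00543 simulated, a difference of -0.0106. For TLX+siCTL and TLX+siTLX against control cells the Pearson correlation was 0.779, the Spearman correlation 0.743 and the simulated value 0.499, and the covariance was 0.290 against 0.00542, a difference of 0.284. Both differences have the simulated covariance taken off, as far as the fitted spread holds. This takes off sampling noise of the shared libraries only. The log2 fold change of TLX+siTLX against control cells is the sum of those of the steps. Its covariance with TLX+siCTL against control cells thus contains the variance of that step itself. A positive value follows unless the siRNA step cancels enough of that step. So 0.290, the correlations of 0.779 and 0.743 and the 5872 rows are no separate evidence that changes with TLX lasted. Part of the overlap counts may still come from the shared libraries.

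**Figure D3:**
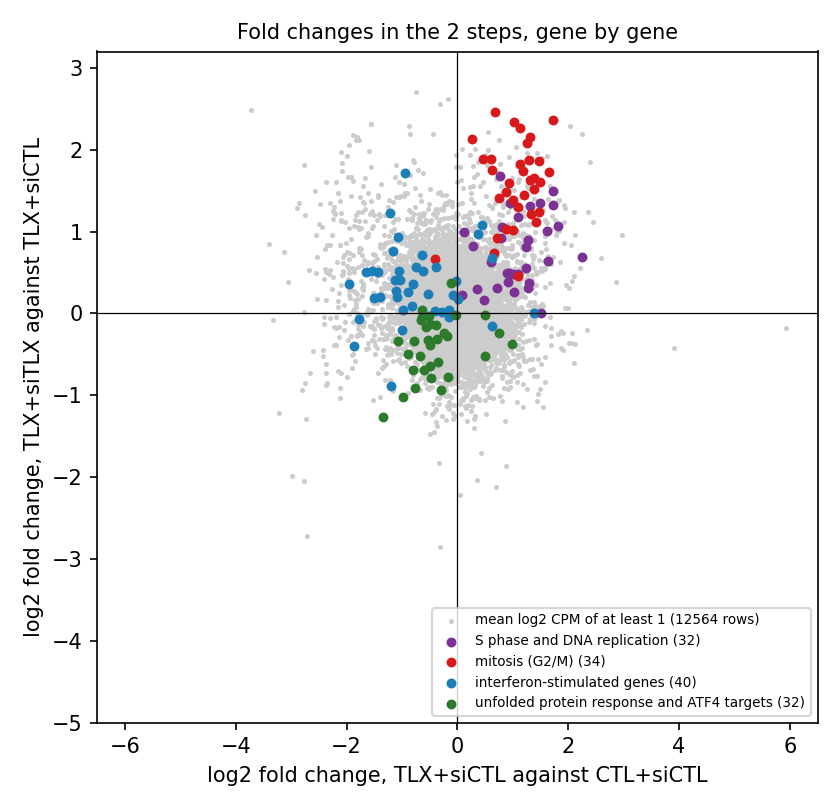
Log2 fold change of TLX+siTLX against TLX+siCTL (vertical) and of TLX+siCTL against CTL+siCTL (horizontal) for the 12564 rows with a mean log2 CPM of at least 1 (grey), with the genes of 4 lists coloured. Most mitosis genes lie in the upper right, with 30 of 34 called up in both steps.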

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

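The settings chosen only after the data were seen were voom on rebuilt reads, the ratio of NR2E1 reads with each library left out, 1 row per symbol, centring on genes with a mean log2 CPM of at least 1, quantile normalization for the lists, summed rows, other backgrounds and leaving out genes with the 7-mer. A minimum absolute log2 fold change of 1 left 1731, 946 and 2365 genes in the 3 comparisons (TLX+siCTL against CTL+siCTL, TLX+siTLX against TLX+siCTL, TLX+siTLX against CTL+siCTL), 210 with opposite changes and 1028 changed the same way in both TLX groups; this follows from the stricter rule. For NR2E1 in TLX+siTLX against CTL+siCTL the log2 fold change was 0.18 with log2(CPM + 1) (adjusted p = 0.387), a scale that shrinks low values, and 1.45 to 2.27 with each replicate left out (1.80 without S1, adjusted p = 0.0549; the cause was not tested). The other NR2E1 calls held in every setting run. With each library left out the comparisons gave 7033 to 8664, 5219 to 6241 and 8312 to 9209 genes, and in the other settings without a fold minimum 7492 to 8593, 5197 to 7526 and 8508 to 9731. Of the 42 list calls, 0 held with camera at an estimated correlation, and 9 with that and all rows as the background, namely S phase (0.0467) in the first comparison, S phase, mesenchymal and integrin genes (0.0202 each), mitosis (0.0298) and hypoxia (0.0422) in the second, and S phase (0.0257), mitosis (0.0496) and antigen presentation (0.0461) in the third. Among the list calls and named genes no direction turned in any setting run. Of the named-gene tests, 59 lost and 4 gained a call with 1 library left out and 3834 did neither, 12 lost and 1 gained a call with library medians centred, and 10 lost and 1 gained a call from the 6 libraries alone. With each library left out, list counts of 1 or 2 genes against the list's direction also moved. They went to 0 to 2 in TLX+siCTL against CTL+siCTL (antigen presentation, ribosomal and epithelial genes). In TLX+siTLX against TLX+siCTL they went to 1 to 2 (integrin and interferon-stimulated genes) and 0 to 1 (cholesterol synthesis genes). For ribosomal genes in TLX+siTLX against CTL+siCTL the count went to 0 to 1. No paired analysis was possible because the table's columns carry no replicate number that the labels give, so the planned replicate block was not run. Genes near the floor, NR2E1 in control cells among them, rest on few reads, and their fold changes depend on the prior count.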

Other observations

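Of the tests here, that of exchanged columns and the share of genes with the 7-mer that fell were chosen only after the result was seen, and quantile normalization of the lists was added after the data were seen but before its own result. Among lists not described so far, no camera call was made in any of the 3 comparisons for other nuclear receptors, of which 13 of 32 fell and 4 rose in TLX+siCTL against CTL+siCTL (14 and 5 adjusted over the list alone; adjusted p = 0.126), with RARG at -1.24 ± 0.05, NR2F1 at -2.07 ± 0.10 and NR2F2 at 1.47 ± 0.08. Matrix proteolysis genes had 12 of 27 fallen and 7 risen there (16 and 7 adjusted over the list alone; adjusted p = 0.236), with the metalloproteinase ADAM19 at -1.57 ± 0.07 and the urokinase receptor PLAUR at -1.08 ± 0.06, and 12 risen and 5 fallen in TLX+siTLX against TLX+siCTL (12 and 8 adjusted over the list alone; adjusted p = 0.238). Apoptosis regulators had 8 risen and 8 fallen of 27 in TLX+siTLX against TLX+siCTL (9 and 9 adjusted over the list alone; adjusted p = 0.755), with the death ligand TNFSF10 at 2.01 ± 0.11 and BBC3 at -0.72 ± 0.07. CDK inhibitor and p53 target genes had 7 risen and 8 fallen of 25 (7 and 9 adjusted over the list alone; adjusted p = 0.685; median -0.04, mean 0.01), with CDKN2C at 1.28 ± 0.08. Of 17 RNA interference genes 3 fell and 1 rose (the same adjusted over the list alone, adjusted p = 0.612, median 0.00, mean -0.06), with AGO1 at -0.60 ± 0.06. In TLX+siCTL against CTL+siCTL the fry adjusted p was 0.000102 (down) for other nuclear receptors and 0.00212 (down) for matrix proteolysis genes. In TLX+siTLX against TLX+siCTL fry gave 0.000275 (up) for matrix proteolysis genes and 0.00253 (up) for apoptosis regulators. For CDK inhibitor and p53 target genes it gave 0.962, and for RNA interference genes 0.287.

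Genes linked to TLX by background knowledge rose in 3 and fell in 3 of 11 cases in TLX+siCTL against CTL+siCTL (3 and 3 adjusted over the list alone; adjusted p = 0.504), with CCND1 at 0.99 ± 0.05 and the CDK inhibitor CDKN1A at -0.50 ± 0.06, and TLX partner genes rose in 4 and fell in 2 of 10 (4 and 2 adjusted over the list alone; adjusted p = 0.673). Neural genes rose in 2 and fell in 2 of 11 (3 and 3 adjusted over the list alone; adjusted p = 0.883; median -0.09, mean 0.03) and Wnt targets rose in 7 and fell in 7 of 18 (8 and 7 adjusted over the list alone; adjusted p = 0.75; median 0.10, mean -0.25). Blood and endothelial markers fell in 1 of 7 cases (1 adjusted over the list alone, adjusted p = 0.67). By fry the adjusted p was 4.3e-05 (up) for TLX-linked genes, 0.00877 (up) for partner genes and 0.0332 (up) for Wnt targets. The TLX-linked genes had a median log2 fold change of 0.03 and a mean of 0.32, and as many rose as fell. Their fry result is thus no rise of most members. For neural genes fry gave 0.752, and for blood and endothelial markers 0.334.

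Cell cycle genes were higher in TLX+siCTL than in CTL+siCTL and higher again in TLX+siTLX, where NR2E1 was lower. Library scaling as the cause is argued against by the smallest median of the mitosis and S phase lists over both steps with quantile normalization, 0.642. Exchanged columns of the TLX groups are argued against by NR2E1, whose lowest log2 CPM in TLX+siCTL was 0.927 above the highest in TLX+siTLX. Of 63 mitosis and S phase genes searched, 3 hold the 7-mer of the scan described next. Other effects of the siRNA than on TLX, beyond that scan, were not tested. How these genes depend on the TLX level and what PC3 in the control titles stands for were not tested either. Nor were differences in culture density or state between the groups, and all of these stay open.

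Genes lower in TLX+siTLX than in TLX+siCTL may include targets of the siRNA by partial matching in 3' UTRs, as a hypothesis. Of 15632 7-mers in 3' UTRs, ACACTCT had the lowest z in that comparison (-11.23, against -4.60 as the lowest in 100 shuffles and 0.355 for it in TLX+siCTL against CTL+siCTL). Of 941 genes that hold it 39.1% fell, against 21.1% of 10234 others, which describes the same fold changes that picked the 7-mer and is no further test. The 7-mer, looked for there after the scan, also lies in NR2E1, in the coding part of exon 6 (chromosome 6, 108180399 to 108180405) and the part of exon 1 that is not coding (108166317 to 108166323), where 17.4% of the tested 7-mers occur in the whole transcript of 3212 bases, 6.83% in its coding part and 1.78% there followed by A, as the exon 6 site is, and the siRNA's sequence is not given in the sources used here. Among the 10 genes with the largest named falls 2 hold it, CYP1A1 and MTMR12, against 8.42% of all genes scanned, and changes downstream of such targets were not tested.

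For the F test over the 3 groups, 1 of 100 splits of the 9 libraries, the real one, gave as many genes (11203, highest other 4777). That argues against a random assignment of these libraries to groups. The labels do not say whether the replicates were separate cultures, so chance differences between cultures cannot be excluded. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05: 1 split, the real one, gave as many genes in each comparison, 8512, 5197 and 8508 genes from the 6 libraries alone, and the highest other splits gave 30, 28 and 38.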
